A study of Homo sapiens with 12 samples.

How the data were processed

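RNA was measured in SNU1079, a human intrahepatic cholangiocarcinoma cell line with mutant IDH1, in 12 libraries of 4 groups with 3 replicates each. Per the labels' protocols, cells were cultured for 5 days with vehicle (DMSO) or with 1 µM AG120 (ivosidenib, an inhibitor of mutant IDH1), and interferon gamma at 10 ng/mL was added for the last 2 days in the groups IFNg and AG120_IFNg. Per the labels' protocols, RNA was extracted with TRIzol and sequenced as directional total RNA libraries after removal of ribosomal RNA. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

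Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.36, kallisto 0.46.0 and the genome build hg38 were used; which step made which file, the gene annotation and the way transcripts were summed are not given in the sources used here. The deposited gene table holds expected counts, that is, read counts the authors estimated per gene symbol, which are not whole numbers throughout. The deposited element table also holds expected counts, given per annotated copy of a repeat and per read strand, and it is named for SQuIRE, a tool that assigns reads to repeat copies and whose version is not given in the sources used here. Neither table was normalised between libraries. The element table has no column of uniquely mapped reads, and reads shared between near-identical copies or genes (C4A and C4B, HLA genes, the MAGEA and GAGE families, histone genes) were divided by the authors' software in a way that cannot be undone here.

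Counts were rounded to whole numbers. Genes were kept by filterByExpr in edgeR 4.0.16 (minimum count 10, by group), which left 20384 genes, and scaled by TMM. All 12 libraries entered 1 fit with 4 group means and 8 residual degrees of freedom. Each contrast was tested with edgeR's quasi-likelihood F test (trended dispersion), and p was adjusted within the contrast by the Benjamini-Hochberg method at a threshold of 0.05. The 5 contrasts were AG120 vs DMSO, IFNg vs DMSO, AG120_IFNg vs IFNg, AG120_IFNg vs AG120, and the interaction, which is the inhibitor's effect with interferon minus its effect without.

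Element counts were summed per repeat subfamily, and also tested per copy, with the same fit. They were scaled by the effective library sizes of the gene table, so that a shift of all elements against all genes was kept; scaling by TMM on the element table itself removes such a shift and was run beside it. Copies were placed against the genes of GENCODE 29 with bedtools 2.31.1. Totals per repeat class, in CPM of effective gene counts, were compared by exact permutation tests of 3 against 3, whose smallest p is 0.1.

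Fixed gene lists (25) and element lists (22, of which 21 had members to test) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between members, and with an estimated correlation and fry as alternatives. Camera compares a list with all other genes, whereas fry asks whether the members move, on balance, one way. Counts of list members were taken from the gene test over all genes and also adjusted over the list alone. The groups, contrasts, lists, alternatives to try and the rule for named genes were set before the data were examined.

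The rule named, for each contrast, the 6 largest rises and 6 largest falls past the threshold with non-overlapping groups and a mean log2 CPM of at least 0 (for the interaction without the overlap condition), from each list the 2 passing members with the largest change and the same minimum level, and 21 fixed genes. For elements it named the 5 largest rises and falls among subfamilies (mean log2 CPM of at least 0) and copies (at least -1), with a summary of 4 element groups. Copies outside annotated genes were named after their values were seen. The fixed genes IFNB1, with at most 6 counts in a library, and ALB, with at most 3, were too low to test. Some named genes are not reported here.

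The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, only the 2 groups compared, the replicate number as a block, each library left out in turn, and for elements their own TMM scaling, no TMM factor, a higher minimum count and only copies outside genes. An alternative with reads on the element's own strand, one without ribosomal DNA regions and unplaced scaffolds, and list tests without AG120_IFNg replicate 3 were added after the data were seen. The procedure was tested on simulated data, in which features were raised or lowered by a set fold. Only a small part of the genes was changed, and every feature had the dispersion of the trend. The rates of recovery and of false calls may therefore differ in the real data. Genes changed 4-fold were recovered in 90.8% to 98.5% of cases in the 4 group contrasts and in 78.8% for the interaction. Genes changed 1.5-fold were recovered in 53.9% to 66.2% and 50%, and subfamilies changed 1.5-fold in 91.0% to 95.5% and 74.2%. Single copies changed 2-fold were recovered in at most 7.81% of cases. False calls with edgeR made up 3.66% to 7.23% of the calls for genes, 3.05% to 6.34% for subfamilies and up to 9.80% for copies. Of the simulated lists, 5 of 5 raised lists and 1 of 20 unchanged lists were called. The simulated genes were drawn independently, so this cannot show how often camera errs on lists of correlated members. The mitochondrially encoded genes, for example, had an estimated correlation of 0.967.

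Levels are given as CPM, counts scaled to the effective library as edgeR defines them, with the standard deviation (SD) over 3 replicates. Log2 fold changes are given with a value called the standard error (SE). It is the absolute log2 fold change divided by the square root of the quasi-likelihood F, and so only approximates a standard error. Where a group has few counts, as for MAGEA4 in DMSO, it can be smaller than the counting error and understates the uncertainty. Per library, 3 counts, taken as the floor for a count of 0, correspond to 0.0304 to 0.0411 CPM; such floors cover counting error only. A fold against a group at 0 in all 3 libraries is given as a lower bound from that floor. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.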

Results

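Gene and transposable element RNA was compared in SNU1079 cholangiocarcinoma cells treated with vehicle (DMSO), interferon gamma (IFNg), the mutant IDH1 inhibitor ivosidenib (AG120) or both (AG120_IFNg), with 3 libraries in each group. Totals in the gene table were 69893556 to 98422514 counts per library, with 23875 to 24811 genes detected. The first principal component of the tested genes held 54.1% of the variance and the second 21.8%. Transcripts encoded in mitochondria made up 2.58% ± 0.158 of gene counts in DMSO, 2.09% ± 0.251 in IFNg, 2.47% ± 0.264 in AG120 and 1.11% ± 0.599 in AG120_IFNg (SD, n = 3 each), with 0.436% in AG120_IFNg replicate 3.

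**Figure D1:**
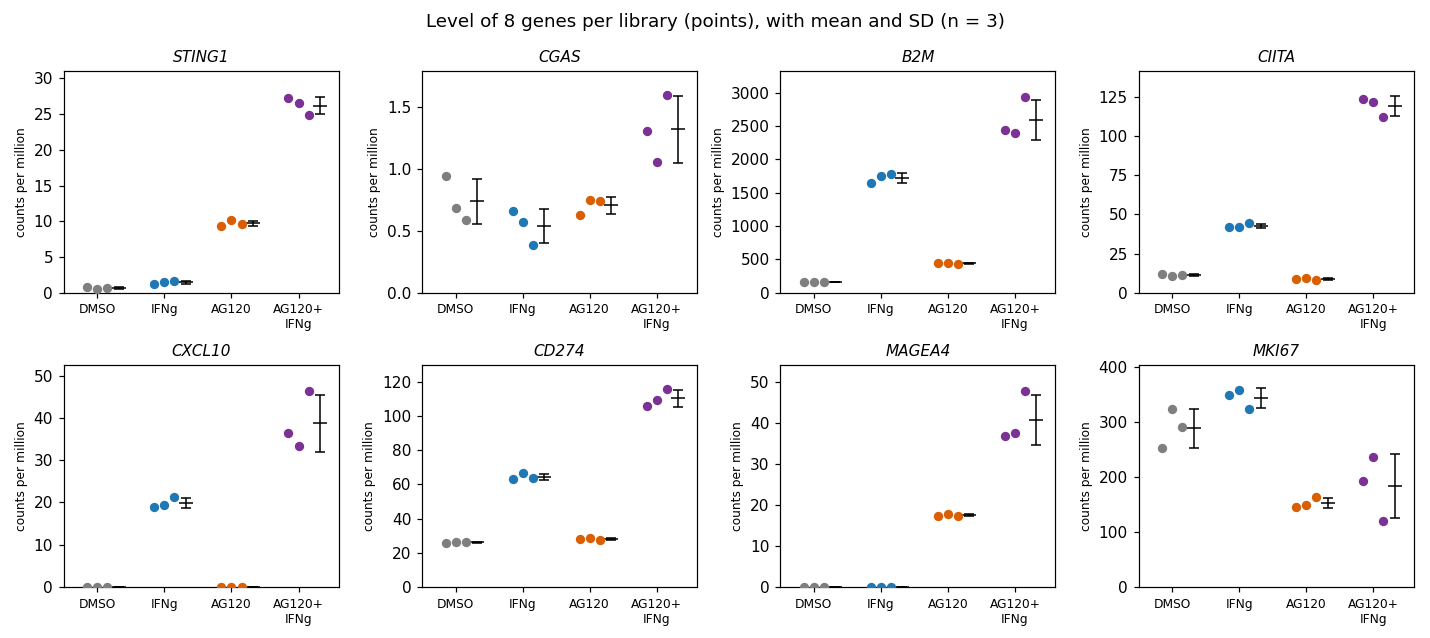
Levels of STING1, CGAS, B2M, CIITA, CXCL10, CD274, MAGEA4 and MKI67 in each library, in CPM on linear axes from 0; points are libraries, and lines beside them show the mean and 1 SD (n = 3 per group).

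The comparison of AG120 with DMSO asks what inhibiting mutant IDH1 changed in these cells without interferon. MAGEA4, a cancer-testis antigen (chromosome X, 151912509 to 151925170, hg38), was among the largest rises and went from 0.0551 ± 0.0480 to 17.5 ± 0.265 CPM (SD, n = 3 each), a log2 change of 8.29 ± 0.23 (SE; adjusted p = 1.22e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). STING1, the adaptor of cytosolic DNA sensing, also rose without any added interferon, from 0.669 ± 0.0900 to 9.72 ± 0.378 CPM. B2M, the light chain of MHC class I, rose from 163 ± 3.92 to 441 ± 4.22 CPM (SD, n = 3). Genes of the cell cycle fell, such as NUSAP1, a spindle protein, by a log2 change of -1.06 ± 0.15 (SE), while CDKN1A, the cell cycle inhibitor p21, rose by 1.72 ± 0.06.

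Among the other largest rises, PNMA6E (chromosome X, 153395640 to 153401420) and PNMA5 (chromosome X, 152988824 to 152994127) belong to a family related to retrotransposon gag genes. PNMA6E went from 0 in the DMSO libraries to 17.0 ± 0.493 CPM (SD, n = 3), at least 450.4-fold from the 3-count floor per library, and PNMA5 rose by a log2 change of 7.33 ± 0.24 (SE). FLNC, an actin cross-linker (chromosome 7, 128830377 to 128859274), rose by 7.33 ± 0.13 to 139 ± 2.89 CPM, MSLN, a cell surface glycoprotein, by 7.07 ± 0.22, and CLDN6, a tight junction protein, by 6.75 ± 0.11. The largest falls included DHRS2, a short-chain dehydrogenase (chromosome 14, 23630115 to 23645639), at a log2 change of -2.12 ± 0.07, ERBB4, a receptor tyrosine kinase, at -1.99 ± 0.13, and CNTNAP2, a cell adhesion protein, at -1.79 ± 0.07.

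Of the 42 tested germline and cancer-testis genes, 34 rose and 1 fell, with a median log2 change of 3.06 (2.81 with genes at 0 in one group set to their bound; camera, adjusted p = 2.23e-14, and 0.000323 with an estimated correlation). MAEL, which acts in transposon silencing in the germline, rose by 5.03 ± 0.15 (SE) to 6.43 ± 0.261 CPM (SD, n = 3). Reads of the near-identical MAGEA and GAGE members cannot be assigned with certainty. Where no second count is given for a list here and in the paragraphs that follow, the count adjusted over the list alone was the same.

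All 22 MHC class I genes rose in AG120 (median log2 change 0.77; camera, adjusted p = 1.06e-11, and 0.0223 with an estimated correlation). HLA-B was higher by 1.44 ± 0.07 (SE) and NLRC5, the transactivator of these genes, by 1.19 ± 0.07; reads shared between HLA genes leave single HLA values less certain. Interferon gamma targets rose in 24 of 30 cases and fell in 2 (26 and 3 adjusted over the list alone; camera, adjusted p = 1.03e-09, and 0.0223 with an estimated correlation). IRF1, a transcription factor of the pathway, was at 0.39 ± 0.05. Of the type I interferon-stimulated antiviral genes 25 of 38 rose and 7 fell (camera, adjusted p = 9.34e-06, and 0.00687 with an estimated correlation). IFI27 rose to 16.7 ± 1.05 CPM (SD, n = 3). Interferon-linked cell death genes rose in 16 of 20 cases and fell in 2 (16 and 3 adjusted over the list alone; camera, adjusted p = 2.34e-05, and 0.00972 with an estimated correlation). CASP1, which activates interleukin 1 beta, was at 2.61 ± 0.09. Chemokines and cytokines rose in 13 of 27 cases and fell in 4 (camera, adjusted p = 0.00327, and 0.0223 with an estimated correlation). IL6 was at 4.25 ± 0.16. T cell inhibitory ligands and enzymes rose in 14 of 20 cases and fell in 1 (15 and 1 adjusted over the list alone; camera, adjusted p = 0.000389, and 0.0191 with an estimated correlation). PDCD1LG2, the PD-L2 ligand, was at 2.00 ± 0.08. CD274, the PD-L1 ligand, stood at 28.1 ± 0.546 against 26.1 ± 0.348 CPM (SD, n = 3; adjusted p = 0.0689, and 0.0176 without AG120_IFNg replicate 3, edgeR's quasi-likelihood test). CGAS, the cytosolic DNA sensor upstream of STING1, was at 0.707 ± 0.0689 against 0.741 ± 0.182 CPM (adjusted p = 0.841).

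Of 34 cell cycle and mitosis genes, 32 fell (median -0.67; camera, adjusted p = 8.22e-16, and 0.0223 with an estimated correlation), and MKI67, a proliferation marker, went from 289 ± 35.7 to 153 ± 8.75 CPM (SD, n = 3). Targets of p53 and cell cycle inhibitors rose in 18 of 23 cases and fell in 2 (19 and 2 adjusted over the list alone; camera, adjusted p = 8.10e-07, and 0.0223 with an estimated correlation). GDF15, a stress-induced cytokine, was at 1.56 ± 0.06 (SE). Replication-dependent histones fell in 18 of 27 cases and rose in 5, with a median of -0.75 and a mean of -0.05 (camera, adjusted p = 0.000420; adjusted p = 0.278 with an estimated correlation). Hepatocyte genes rose in 12 of 26 cases and fell in 3 (camera, adjusted p = 0.0267; adjusted p = 0.157 with an estimated correlation), led by the fibrinogen chains FGA at 4.94 ± 0.12 and FGG at 4.25 ± 0.10. Biliary genes rose in 14 of 27 cases and fell in 5 (14 and 6 adjusted over the list alone; camera, adjusted p = 0.00798; adjusted p = 0.195 with an estimated correlation). KRT23, a keratin, was at 3.72 ± 0.10. Cholesterol and fatty acid synthesis genes rose in 15 of 26 cases and fell in 1 (camera, adjusted p = 0.00147; adjusted p = 0.215 with an estimated correlation). Hypoxia and glycolysis genes rose in 14 of 29 cases and fell in 5 (14 and 6 adjusted over the list alone; camera, adjusted p = 0.0348; adjusted p = 0.215 with an estimated correlation). Stress and unfolded protein response genes rose in 14 of 27 with 5 falls (15 and 5 adjusted over the list alone; camera, adjusted p = 0.0314; adjusted p = 0.302 with an estimated correlation).

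Several lists had no camera call, and most of these had members that moved in both directions. NF-kB targets rose in 7 and fell in 9 of 21 cases (median -0.04, mean 0.06; camera, adjusted p = 0.535), with LCN2, an iron-sequestering secreted protein, at 3.14 ± 0.17 (SE) and TRAF1, a signalling adaptor, at -1.37 ± 0.07. YAP targets and mesenchymal genes rose in 13 and fell in 6 of 28 cases (13 and 8 adjusted over the list alone; camera, adjusted p = 0.194), and CDH1, the epithelial E-cadherin, rose from 4.12 ± 0.163 to 66.3 ± 1.18 CPM (SD, n = 3). Nucleic acid sensing genes rose in 13 and fell in 5 of 28 cases (13 and 7 adjusted over the list alone; camera, adjusted p = 0.0646). Transposon silencing genes rose in 4 and fell in 10 of 25 cases (5 and 10 adjusted over the list alone; camera, adjusted p = 0.0646), among them ZNF93, a repressor of L1 elements, at -0.98 ± 0.12. Enzymes of DNA methylation and 2-oxoglutarate metabolism rose in 13 and fell in 7 of 33 cases (13 and 8 adjusted over the list alone; camera, adjusted p = 0.559), with IDH1 itself at 0.43 ± 0.08 and DNMT1, the maintenance methyltransferase, at -0.34 ± 0.07. MHC class II genes rose in 5 and fell in 4 of 14 cases (6 and 4 adjusted over the list alone; median -0.04, mean 0.62; camera, adjusted p = 0.831), and their transactivator CIITA fell from 11.4 ± 0.778 to 8.73 ± 0.630 CPM. Xenobiotic metabolism genes rose in 10 and fell in 4 of 21 cases (10 and 5 adjusted over the list alone; camera, adjusted p = 0.0594). Leukocyte markers rose in 6 and fell in 2 of 17 tested cases (camera, adjusted p = 0.182), including CD79A, a B cell receptor chain, and CD68, a lysosomal protein of macrophages, and fibroblast and endothelial markers rose in 8 and fell in 4 of 17 (camera, adjusted p = 0.209). None of the 13 mitochondrially encoded genes passed the threshold, and their median log2 change was -0.25 (camera, adjusted p = 0.430). Fry, which asks whether the members move on balance one way, called 7 of these 10 lists. Its adjusted p was 6.85e-07 for nucleic acid sensing, 3.81e-06 for YAP targets, 3.63e-08 for xenobiotic metabolism, 0.000380 for leukocyte and 5.34e-06 for fibroblast and endothelial markers (higher), and 0.00760 for NF-kB targets and 3.02e-05 for transposon silencing (lower).

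In total, 9685 of 20384 tested genes passed the threshold in AG120 vs DMSO, 5313 of them higher and 4372 lower, and 1310 rose and 689 fell by at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). The 3 libraries of one group all lay above the 3 of the other for 62.2% of the tested genes, where chance gives 10%. With 3 libraries per group, changes of 1.5-fold were recovered in 66.2% of simulated genes. Far fewer genes were changed in that simulation than passed here, so this rate is not the power in these data.

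The comparison of IFNg with DMSO shows the response of the cells to interferon gamma alone. CXCL9, a chemokine that attracts T cells (chromosome 4, 76001275 to 76007488), was at 0 in the DMSO libraries and at 47.9 ± 2.55 CPM in IFNg (SD, n = 3), at least 1265-fold higher (adjusted p = 2.44e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HLA-DRA, a chain of MHC class II (chromosome 6, 32439842 to 32445046), went from 0 to 35.2 ± 1.22 CPM, at least 931-fold. GBP5, an interferon-induced GTPase, rose by a log2 change of 7.56 ± 0.08 (SE), CXCL10 by 8.37 ± 0.27, and CD74, the class II invariant chain, by 7.99 ± 0.41 to 313 ± 19.0 CPM. IRF1 rose from 51.3 ± 1.62 to 656 ± 3.67 CPM (SD, n = 3).

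The largest falls in IFNg included those of KRT75, a keratin, at -2.89 ± 0.15 (SE), CRCT1 at -2.87 ± 0.25 and TNFAIP6, a hyaluronan-binding protein, at -2.68 ± 0.22. Type I interferon-stimulated antiviral genes rose in 35 of 38 cases (median 2.95; camera, adjusted p = 4.46e-43, and 4.79e-06 with an estimated correlation). Interferon gamma targets rose in 25 of 30 (median 2.66, and 2.63 with genes at 0 at their bound; camera, adjusted p = 4.31e-33, and 0.000868 with an estimated correlation). MHC class I genes rose in 21 of 22 (median 2.58; camera, adjusted p = 1.52e-30, and 0.00173 with an estimated correlation). MHC class II genes rose in 13 of 14 cases and fell in 1 (median 3.15; camera, adjusted p = 4.52e-15, and 0.00267 with an estimated correlation), with CIITA from 11.4 ± 0.778 to 42.6 ± 1.42 CPM (SD, n = 3). Nucleic acid sensing genes rose in 21 of 28 cases and fell in 1 (camera, adjusted p = 2.42e-14, and 0.00108 with an estimated correlation), led by IFIH1 and TLR3, sensors of double-stranded RNA, at 2.50 ± 0.06 and 2.46 ± 0.05, with STING1 at 1.15 ± 0.13. Interferon-linked cell death genes rose in 13 of 20 cases (camera, adjusted p = 1.98e-10, and 0.000868 with an estimated correlation). CASP1 was at 4.12 ± 0.09. Chemokines and cytokines rose in 12 of 27 cases and fell in 3 (13 and 4 adjusted over the list alone; camera, adjusted p = 0.000702, and 0.0121 with an estimated correlation). T cell inhibitory ligands and enzymes rose in 9 of 20 cases and fell in 3 (9 and 4 adjusted over the list alone; camera, adjusted p = 0.00771, and 0.0397 with an estimated correlation). IDO1, which degrades tryptophan, was at 5.62 ± 0.16 and CD274 at 1.31 ± 0.05.

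Cell cycle genes rose in 21 of 34 cases (23 adjusted over the list alone; camera, adjusted p = 4.76e-08; adjusted p = 0.115 with an estimated correlation). Stress and unfolded protein response genes rose in 13 of 27 with 1 fall (14 and 1 adjusted over the list alone; camera, adjusted p = 0.000214; adjusted p = 0.137 with an estimated correlation). ATF3, a stress-induced transcription factor, was at 1.25 ± 0.05 (SE). Fibroblast and endothelial markers fell in 7 of 17 cases and rose in 2 (2 and 8 adjusted over the list alone for rises and falls; camera, adjusted p = 0.00771, and 0.0473 with an estimated correlation). PDGFRB, a growth factor receptor, was at -1.43 ± 0.13. Histone genes rose in 7 of 27 cases and fell in 1, with camera adjusted p = 0.0546, 0.589 with an estimated correlation and 0.0238 without AG120_IFNg replicate 3 (fry, adjusted p = 0.128). Germline genes rose in 2, fell in 3 and did not pass in 37 of 42 cases (1 and 3 adjusted over the list alone; camera, adjusted p = 0.777). In total 6412 genes passed the threshold, 3268 higher and 3144 lower, with 445 rises and 491 falls of at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap for 52.8% of the tested genes, where chance gives 10%.

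The comparison of AG120_IFNg with IFNg asks what the inhibitor changed in cells that received interferon gamma. MAGEA4 rose from 0.0562 ± 0.0168 to 40.7 ± 6.10 CPM (SD, n = 3), a log2 change of 9.45 ± 0.22 (SE; adjusted p = 2.26e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). PNMA6E at 9.38 ± 0.15, FLNC at 8.87 ± 0.15, PNMA5 at 8.82 ± 0.25 and NRK, a protein kinase (chromosome X, 105822543 to 105958610), at 7.49 ± 0.12 were further large rises. STING1 rose from 1.48 ± 0.214 to 26.2 ± 1.22 CPM, CIITA from 42.6 ± 1.42 to 119 ± 6.22 CPM, and IDO1 from 22.1 ± 1.01 to 117 ± 19.7 CPM (SD, n = 3). The largest falls included DOCK2, an activator of Rac (chromosome 5, 169637247 to 170083382), at -2.91 ± 0.05, CDK15 at -2.87 ± 0.18 and BMP6, a growth factor, at -2.44 ± 0.09.

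Type I interferon-stimulated antiviral genes rose in 37 of 38 cases (median 1.24; camera, adjusted p = 7.11e-17, and 0.000139 with an estimated correlation). SAMD9 was at 3.38 ± 0.11 (SE) and OASL at 2.79 ± 0.11. All 14 MHC class II genes rose (median 1.81; camera, adjusted p = 1.22e-07, and 0.0175 with an estimated correlation). HLA-DPB1 was at 2.41 ± 0.15. Interferon gamma targets rose in 25 of 30 cases (26 adjusted over the list alone; camera, adjusted p = 4.84e-10, and 0.0175 with an estimated correlation). SECTM1, a ligand of T cells, was at 5.52 ± 0.16 (5.515). MHC class I genes rose in 16 of 22 cases (median 0.35; camera, adjusted p = 2.37e-05; adjusted p = 0.0908 with an estimated correlation). HLA-B was at 1.12 ± 0.07 (1.115). Nucleic acid sensing genes rose in 21 of 28 cases and fell in 2 (22 and 2 adjusted over the list alone; camera, adjusted p = 9.03e-06, and 0.0175 with an estimated correlation). ZBP1, a sensor of left-handed nucleic acids, was at 2.12 ± 0.13 (2.115). Chemokines and cytokines rose in 20 of 27 cases and fell in 3 (camera, adjusted p = 3.13e-05, and 0.00765 with an estimated correlation). CXCL16 was at 4.32 ± 0.21. T cell inhibitory ligands and enzymes rose in 13 of 20 cases (13 rises and 1 fall adjusted over the list alone; camera, adjusted p = 4.47e-05, and 0.00838 with an estimated correlation). CD274 was at 0.77 ± 0.04. Cell death genes rose in 18 of 20 cases and fell in 1 (camera, adjusted p = 1.42e-07, and 0.00264 with an estimated correlation).

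Germline genes rose in 35 of 42 cases (median 3.33, and 3.16 with genes at 0 at their bound; camera, adjusted p = 3.99e-15, and 0.000139 with an estimated correlation). Cell cycle genes fell in 32 of 34 cases (camera, adjusted p = 2.07e-16, and 0.0192 with an estimated correlation). PLK1, a mitotic kinase, was at -1.38 ± 0.08 (SE), and p53 targets rose in 18 of 23 and fell in 2 (camera, adjusted p = 4.67e-07, and 0.0175 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell in 19 of 26 cases (median -0.33; camera, adjusted p = 1.42e-07; adjusted p = 0.0545 with an estimated correlation). NF-kB targets rose in 12 and fell in 2 of 21 cases (camera, adjusted p = 0.00556; adjusted p = 0.0856 with an estimated correlation). Hepatocyte genes rose in 13 and fell in 4 of 26 (camera, adjusted p = 0.0227; adjusted p = 0.117 with an estimated correlation). Stress genes rose in 18 and fell in 4 of 27 (19 and 5 adjusted over the list alone; camera, adjusted p = 0.000795; adjusted p = 0.133 with an estimated correlation). Leukocyte markers rose in 8 of 17 cases (camera, adjusted p = 0.0227; adjusted p = 0.187 with an estimated correlation). Transposon silencing genes fell in 13 and rose in 6 of 25 cases (13 and 7 adjusted over the list alone), with camera adjusted p = 0.0420, 0.185 with an estimated correlation and 0.0744 without AG120_IFNg replicate 3. Xenobiotic metabolism genes rose in 11 and fell in 3 of 21 cases (11 and 4 adjusted over the list alone), with camera adjusted p = 0.0302, 0.0779 with an estimated correlation and 0.0541 without that library. Fibroblast and endothelial markers rose in 8 and fell in 2 of 17 cases, with camera adjusted p = 0.0307, 0.0908 with an estimated correlation and 0.0563 without that library. Histone genes fell in 20 and rose in 6 of 27 cases, with a median of -0.69 and a mean of 0.58 (camera down, adjusted p = 0.00216; adjusted p = 0.322 with an estimated correlation). Mitochondrially encoded genes fell in 11 of 13 cases (median -1.21; camera, adjusted p = 0.000795; adjusted p = 0.387 with an estimated correlation), where AG120_IFNg replicate 3 held 0.436% of such counts and its partners 1.34% and 1.57%.

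In all, 10018 genes passed the threshold in AG120_IFNg vs IFNg, 5713 higher and 4305 lower, with 1831 rises and 582 falls of at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap for 55.3% of the tested genes, where chance gives 10%. Across the 20384 genes, the inhibitor's log2 changes without and with interferon, which share no library, had a Pearson correlation of 0.821 and a Spearman correlation of 0.682; genes are not independent replicates. Of the genes past the threshold in both, 3943 rose in both, 2553 fell in both and 272 moved in opposite directions, where independence would give 1489 and 923 for the shared rises and falls.

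**Figure D2:**
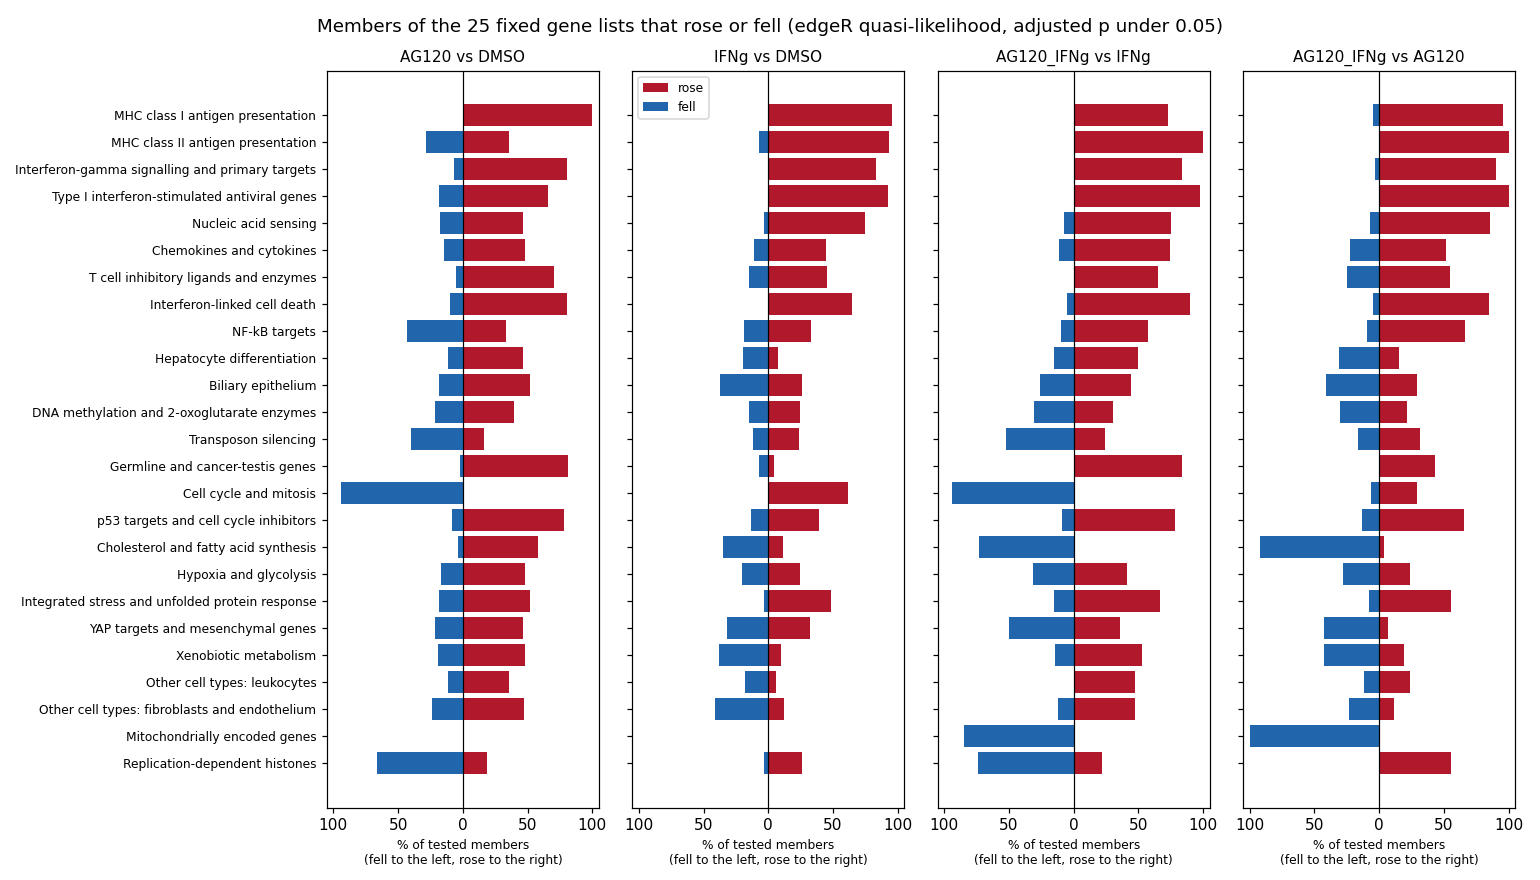
Percentage of the tested members of each of the 25 fixed gene lists that rose (to the right) or fell (to the left) in the 4 group contrasts, by edgeR's quasi-likelihood test with adjusted p under 0.05.

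The comparison of AG120_IFNg with AG120 gives the interferon response of inhibitor-treated cells. CXCL10 was at 0 in the AG120 libraries and at 38.7 ± 6.74 CPM in AG120_IFNg (SD, n = 3), at least 974.1-fold higher (adjusted p = 1.78e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). HLA-DRA rose by a log2 change of 11.42 ± 0.13 (SE) to 162 ± 4.31 CPM, HLA-DRB1 by 8.96 ± 0.16, GBP5 by 8.81 ± 0.09 (8.805) and IDO1 by 8.60 ± 0.17. OAS2, an antiviral enzyme that senses double-stranded RNA, rose from 0.913 ± 0.159 to 284 ± 15.9 CPM, and CIITA from 8.73 ± 0.630 to 119 ± 6.22 CPM (SD, n = 3). The largest falls included CLVS1 (chromosome 8, 61057158 to 61501645) at -3.83 ± 0.11, SLC17A3, a transporter, at -2.71 ± 0.12, KRT75 at -2.67 ± 0.10 and ADAMTS1, an extracellular protease, at -2.42 ± 0.04.

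All 38 type I interferon-stimulated antiviral genes rose (median 3.57; camera, adjusted p = 1.14e-41, and 5.46e-06 with an estimated correlation), as did all 14 MHC class II genes (median 4.91; camera, adjusted p = 1.14e-17, and 0.00186 with an estimated correlation). MHC class I genes rose in 21 of 22 cases and fell in 1 (median 2.18; camera, adjusted p = 2.46e-21, and 0.00476 with an estimated correlation). Interferon gamma targets rose in 27 and fell in 1 of 30 (camera, adjusted p = 1.45e-27, and 0.00124 with an estimated correlation). Nucleic acid sensing genes rose in 24 and fell in 2 of 28 (25 and 2 adjusted over the list alone; camera, adjusted p = 3.97e-15, and 0.00121 with an estimated correlation). Cell death genes rose in 17 and fell in 1 of 20 cases (camera, adjusted p = 1.21e-11, and 0.000790 with an estimated correlation). NF-kB targets rose in 14 and fell in 2 of 21 (15 and 2 adjusted over the list alone; camera, adjusted p = 3.23e-05, and 0.0174 with an estimated correlation). CD40 was at 2.03 ± 0.07 (SE). Chemokines and cytokines rose in 14 and fell in 6 of 27 cases (camera, adjusted p = 0.00224, and 0.0174 with an estimated correlation). T cell inhibitory genes rose in 11 and fell in 5 of 20 (camera, adjusted p = 0.00224, and 0.0178 with an estimated correlation). CD274 was at 1.97 ± 0.05. Germline genes rose in 18 of 42 cases (median 0.49; camera, adjusted p = 0.000367, and 0.00761 with an estimated correlation). MAGEA4 was at 1.22 ± 0.11.

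Cholesterol and fatty acid synthesis genes fell in 24 of 26 cases and rose in 1 (median -0.65; camera, adjusted p = 3.90e-15, and 0.0111 with an estimated correlation), with SCD, the stearoyl-CoA desaturase, from 1066 ± 18.6 to 350.1 ± 11.5 CPM (SD, n = 3). The p53 targets rose in 15 and fell in 3 of 23 cases (camera, adjusted p = 0.00470; adjusted p = 0.135 with an estimated correlation). Stress genes rose in 15 and fell in 2 of 27 (camera, adjusted p = 0.000205; adjusted p = 0.131 with an estimated correlation). DDIT3, a stress-induced transcription factor, was at 1.42 ± 0.06 (SE). YAP targets and mesenchymal genes fell in 12 and rose in 2 of 28 cases (camera, adjusted p = 0.00964; adjusted p = 0.310 with an estimated correlation). Histone genes rose in 15 of 27 cases (16 rises and 1 fall adjusted over the list alone; camera, adjusted p = 0.000113; adjusted p = 0.264 with an estimated correlation). Cell cycle genes rose in 10 and fell in 2 of 34 (camera, adjusted p = 0.0818, and 0.0179 without AG120_IFNg replicate 3; fry, adjusted p = 0.0106). The 13 mitochondrially encoded genes fell (median -1.23; camera, adjusted p = 0.000269; adjusted p = 0.418 with an estimated correlation), beside the share of 0.436% in AG120_IFNg replicate 3. In total 7773 genes passed the threshold, 4157 higher and 3616 lower, with 891 rises and 503 falls of at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap for 47.4% of the tested genes, where chance gives 10%. The interferon changes without and with inhibitor, which share no library, had a Pearson correlation of 0.600 and a Spearman correlation of 0.476 across genes, which are not independent replicates, with 2131 shared rises, 1564 shared falls and 300 opposite changes. For the 10504 genes of a mean log2 CPM of at least 3 the correlations were 0.838 and 0.613. For the inhibitor's changes they were 0.789 and 0.745 in the same genes.

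The interaction asks whether the inhibitor's log2 change differed between cells with and without interferon. A positive value means a more positive log2 change with interferon. It does not compare differences in CPM, which can go the other way for genes that interferon raises strongly. DUOX2, an oxidase that makes hydrogen peroxide (chromosome 15, 45092650 to 45114344), was at 1.37 ± 0.234 CPM in DMSO, 1.35 ± 0.154 in IFNg and 1.34 ± 0.190 (1.345) in AG120 but 38.3 ± 1.97 in AG120_IFNg (SD, n = 3), an interaction of 4.85 ± 0.18 (SE; adjusted p = 2.72e-08, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its maturation factor DUOXA2 had 3.79 ± 0.19 (3.785), LAMP3, a lysosomal membrane protein, 3.38 ± 0.30, MX2, an antiviral GTPase, 2.98 ± 0.17, and KCTD14 2.98 ± 0.28. The MHC class II transactivator CIITA had 1.86 ± 0.09, IDO1 2.98 ± 0.30 and CD274 0.67 ± 0.06. Negative values were found for CLVS1 at -2.10 ± 0.15, TENM2, a cell adhesion protein, at -1.96 ± 0.13 and IFI27 at -1.96 ± 0.18.

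Cholesterol and fatty acid synthesis genes had a negative interaction in 23 of 26 cases (24 adjusted over the list alone; median -0.59; camera, adjusted p = 2.15e-21, and 0.0136 with an estimated correlation). MHC class II genes had a positive one in 9 of 14 cases (9 positive and 1 negative adjusted over the list alone; camera, adjusted p = 2.04e-09, and 0.0167 with an estimated correlation), as had type I interferon-stimulated antiviral genes in 23 of 38 with 6 negative (24 and 8 adjusted over the list alone; camera, adjusted p = 2.23e-07, and 0.00520 with an estimated correlation). NF-kB targets were positive in 11 of 21 cases (12 adjusted over the list alone; camera, adjusted p = 1.16e-05, and 0.0252 with an estimated correlation). TNFAIP3, an inhibitor of this pathway, was at 1.28 ± 0.08 (SE). Nucleic acid sensing genes were positive in 13 and negative in 3 of 28 cases (14 and 3 adjusted over the list alone; camera, adjusted p = 0.000117, and 0.0343 with an estimated correlation). ZBP1 was at 2.59 ± 0.20. Germline genes were positive in 7 and negative in 1 of 42 cases (camera, adjusted p = 0.000569, and 0.0167 with an estimated correlation). MAEL was at 2.06 ± 0.29. MHC class I genes were negative in 14 of 22 cases (15 adjusted over the list alone; camera, adjusted p = 3.70e-08; adjusted p = 0.0583 with an estimated correlation). NLRC5 was at -1.05 ± 0.09 and B2M at -0.85 ± 0.10, and YAP targets and mesenchymal genes in 14 of 28 (15 adjusted over the list alone; camera, adjusted p = 5.79e-08; adjusted p = 0.0583 with an estimated correlation). TAGLN, an actin-binding protein, was at -0.77 ± 0.08.

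The interaction passed the threshold for 2913 genes, positive for 1317 and negative for 1596 (edgeR's quasi-likelihood test, Benjamini-Hochberg), and without AG120_IFNg replicate 3 for 5088.

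Transposable element reads fell relative to gene reads in every treated group. LINE elements, in CPM of effective gene counts, were at 75529 ± 8934 in DMSO, 56111 ± 4353 in IFNg, 53964 ± 2560 in AG120 and 45609 ± 2282 in AG120_IFNg (SD, n = 3), which is 28.6% lower in AG120 and 25.7% lower in IFNg than in DMSO (exact permutation test, p = 0.1 each, the smallest that 3 against 3 can give, and adjusted p = 0.133). Relative to DMSO, SINE elements were 23.1% and LTR elements 25.8% lower in AG120, and 17.5% and 19.7% lower in IFNg (p = 0.1 each in the same exact test). As a share of all element counts instead, the log2 change in AG120 was -0.12 for LINE, -0.01 for SINE and -0.06 for LTR elements. A ratio of element to gene reads cannot show which of the 2 moved.

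Of all counts in the element table, those in genes made up 88.4% and those on the strand of the element 53.6%. By position, LINE, SINE, LTR, DNA and Retroposon elements outside ribosomal DNA regions and unplaced scaffolds were counted. Among these, reads in introns on the strand of the host gene were 14.5% ± 2.23 of effective gene counts in DMSO, 10.4% ± 0.916 in IFNg, 9.55% ± 0.723 in AG120 and 8.08% ± 0.817 in AG120_IFNg (SD, n = 3), and made up 84.2% of the fall with AG120 and 85.3% of that with IFNg. Of the reads counted by position they held 62.6% ± 2.38 in DMSO, 56.8% ± 1.68 in IFNg and 55.4% ± 1.35 in AG120 (SD, n = 3). Reads in exon-overlapping elements were at 4.81%, 4.96%, 4.77% and 4.92% in the same order, and those outside genes at 2.05%, 1.61%, 1.60% and 1.41%. Counts of ANKRD30BL, a gene symbol that takes up ribosomal-like sequence, made up 1.62% to 2.98% of gene counts in DMSO and 0.740% to 1.88% in the other groups, and ribosomal DNA regions and unplaced scaffolds held 6.46% of all counts in the element table.

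**Figure D3:**
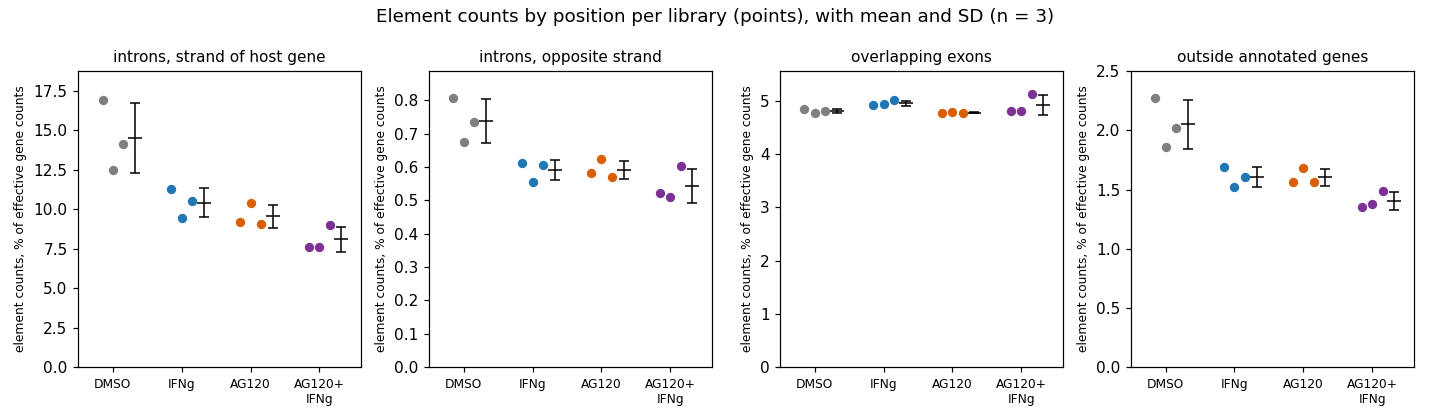
Element counts by position, as a percentage of effective gene counts, on axes from 0; points are libraries, and lines beside them show the mean and 1 SD (n = 3 per group).

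With gene scaling, 12 of 1117 subfamilies rose and 944 fell in AG120 vs DMSO (edgeR's quasi-likelihood test, Benjamini-Hochberg), whereas with element scaling 171 of 1118 rose and 123 fell; gene scaling shifted the median log2 change to -0.49. For IFNg vs DMSO the rises and falls were 32 and 841 with gene scaling against 173 and 101 with element scaling (median -0.41). For AG120_IFNg vs IFNg they were 28 and 479 against 159 and 103 (median -0.27), and for AG120_IFNg vs AG120 67 and 251 against 176 and 113 (median -0.20). In AG120_IFNg vs IFNg the gene-scaled count of 507 became 115 without IFNg replicate 1, 161 without AG120_IFNg replicate 1 and 267 without AG120_IFNg replicate 2. In AG120_IFNg vs AG120 the count of 318 became 147 without AG120 replicate 2, 124 without AG120_IFNg replicate 1 and 193 without AG120_IFNg replicate 2.

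Of the 8 young L1 subfamilies, the elements still able to move in humans among them, 6 fell in AG120 and 8 in IFNg against DMSO with gene scaling (edgeR's quasi-likelihood test), with medians of -0.37 and -0.50, and of 0.10 and -0.08 with element scaling. Of the 6 SVA subfamilies 4 and 3 fell, with medians of -0.24 and -0.27 and of 0.23 and 0.14 with element scaling. HERV-K members fell in 9 of 12 cases in both contrasts with 1 rise in IFNg, with medians of -0.46 and -0.44 and of 0.01 and -0.02 with element scaling. HERV-H members fell in 5 and 4 of 6 cases (5 in both adjusted over the list alone), with medians of -0.42 and -0.31 and of 0.07 and 0.11 with element scaling. Camera, which compares a list with the other elements, called 1 of 21 element lists in IFNg vs DMSO (older L1, lower, adjusted p = 0.0437; adjusted p = 0.982 with an estimated correlation, and 0.0753 with the replicate block) and 1 in the interaction (HERV-H, negative, adjusted p = 0.00569; adjusted p = 0.983 with an estimated correlation). In AG120 vs DMSO camera called 0 lists, with 1 at an unadjusted p under 0.05, while fry found that 20 of 21 fell on balance with gene scaling. With element scaling camera called 3 lists higher (Alu S, SVA and MIR, adjusted p = 0.0388, 0.0373 and 0.0388) and 1 lower (older L1, adjusted p = 0.00360), and fry called 1 (MIR, adjusted p = 0.00859).

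Among named subfamilies, HERVKC4-int, an endogenous retrovirus inside some copies of complement C4 genes, rose by a log2 change of 1.09 ± 0.11 (SE) in AG120 and 2.02 ± 0.11 (2.015) in IFNg against DMSO (edgeR's quasi-likelihood test), but changed by -0.77 and -0.35 when only copies outside genes were counted. HERVL18-int rose by 1.05 ± 0.10 in AG120 and was at -0.16 outside genes. MST-int rose by 2.33 ± 0.14 in IFNg and was at -0.74 outside genes, and LTR48 rose by 1.56 ± 0.10 in IFNg and was at -0.36 there. Falls included LTR71B at -1.21 ± 0.10 and HERV15-int at -1.30 ± 0.12 in AG120, HERV30-int at -1.05 ± 0.14 in IFNg, and LTR7Y and HERVH-int, which make up HERV-H proviruses, at -1.83 ± 0.17 (-1.825) and -1.13 ± 0.16 in AG120_IFNg vs IFNg.

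Single copies with the largest rises lay mostly in annotated genes, while several of those with the largest falls overlapped no annotated gene. Some of these falls, of a MER45C, an SSU-rRNA_Hsa and an L1PA3 copy, lay on unplaced or unlocalized scaffolds with no annotated gene, so these copies could not overlap one. In AG120 vs DMSO the largest named fall was that of a MER45C copy on an unplaced scaffold, at a log2 change of -5.54 ± 0.72 (SE). This copy was at 41.0 ± 43.5 CPM in DMSO (SD, n = 3). In AG120 a MER63C copy in an intron of PROSER2-AS1 (chromosome 10, 11883709 to 11884426) went from 0.0384 ± 0.0486 to 9.38 ± 1.44 CPM (SD, n = 3), a MamGyp-int copy in a coding exon of PNMA5 rose by a log2 change of 7.42 ± 0.29 (SE), and an LTR12D copy in a UTR of DHRS2 fell at -3.26 ± 0.35. In IFNg a MER1B copy in an exon of GBP5 was at least 420.1-fold higher. Outside genes, a MLT1N2 copy on chromosome 5 (14017838 to 14018392), 73295 bases from DNAH5, rose from 0.583 to 10.5 CPM in AG120. Only 2.3% of its reads lay on its own (plus) strand. The adjoining L1P3 copy on the minus strand, with 99.1% of reads on its own strand, also rose, by 3.91 ± 0.20. Reads of both copies thus lay mostly on the minus strand, and whether they come from the same transcript was not tested. A HERVP71A-int copy on chromosome 13 (67340596 to 67348147) rose by 8.88 ± 0.27 in IFNg. HERVH-int copies on chromosome 6 (144923609 to 144926571 and 144926706 to 144927208) fell at -3.12 ± 0.19 and -3.84 ± 0.32 in AG120_IFNg vs IFNg. These copies outside genes were chosen after their values were seen, except the MER45C copy and those on chromosome 6 from 144926706, which the rule named.

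Of 454007 tested copies, 4822 rose and 48644 fell in AG120 vs DMSO with gene scaling (edgeR's quasi-likelihood test, Benjamini-Hochberg), against 13494 and 2936 with element scaling. The corresponding rises and falls were 4530 and 19914 against 9178 and 1985 in IFNg vs DMSO, 5905 and 29147 against 13284 and 7332 in AG120_IFNg vs IFNg, and 6467 and 16712 against 11328 and 6893 in AG120_IFNg vs AG120. Of the 38239 copies outside genes, 1077 rose and 4186 fell in AG120 with gene scaling, and among these the 245 retroposon (SVA) copies had 29 rises and 18 falls. The gene-scaled total of 53466 in AG120 vs DMSO became 15707 without DMSO replicate 1, 29494 without DMSO replicate 3, 21818 without AG120 replicate 1 and 20867 without AG120 replicate 3, and that of 24444 in IFNg vs DMSO became 7578 without DMSO replicate 1, 12595 without DMSO replicate 3, 8362 without IFNg replicate 2 and 10938 without IFNg replicate 3. In AG120_IFNg vs IFNg 35052 became 17546 without IFNg replicate 1, 22410 without IFNg replicate 3 and 22324 without AG120_IFNg replicate 1, and in AG120_IFNg vs AG120 23179 became 14207 without AG120 replicate 2.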

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

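The genes, subfamilies and lists given with an interaction were picked out by the planned test of it, in which the inhibitor's effect differed between cells with and without interferon. The fall of element reads, the library that stood apart and the rise of germline genes were picked after their values were seen. The tests of intron share, of reads on both strands of introns, of groups at the 3-count floor, of gene against element level and of shared reads in germline genes were chosen only after the results were seen.

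The interaction passed for 2913 genes and 26 element subfamilies (edgeR's quasi-likelihood test, Benjamini-Hochberg). Of 100 regroupings of the libraries, 1 gave as many genes, the real grouping itself, and the highest other count was 841. These regroupings mixed libraries of all 4 groups, so the treatment effects enter them. They cannot show how many genes would pass without an interaction. For subfamilies 5 of 100 gave as many, with 896 in the highest other, for gene lists 17 of 100 (14 real, 18 in the highest other) and for element lists 64 of 100 (1 real, 7 in the highest other), so chance is not excluded for these. A regrouping that calls 896 subfamilies points to a structure of the samples, of which the treatments themselves are part, and its cause was not tested.

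Gene lists picked out by the interaction, with camera's adjusted p, were cholesterol and fatty acid synthesis (2.15e-21), MHC class II (2.04e-09), MHC class I (3.70e-08), YAP targets and mesenchymal genes (5.79e-08), type I interferon-stimulated antiviral genes (2.23e-07), NF-kB targets (1.16e-05), nucleic acid sensing (0.000117) and germline genes (0.000569). Further lists were mitochondrially encoded genes (0.000806), cell cycle (0.00112), replication-dependent histones (0.00640), biliary epithelium (0.0227), p53 targets (0.0227) and interferon-linked cell death (0.0445), and among elements HERV-H (0.00569), by the same camera test. With an estimated correlation, adjusted p was 0.0583 for MHC class I and for YAP targets, 0.410 for mitochondrially encoded genes, 0.353 for cell cycle, 0.408 for histones, 0.283 for biliary and for p53 genes, 0.112 for cell death and 0.983 for HERV-H. The cell death list had adjusted p = 0.0513 with the replicate block, and the mitochondrially encoded genes 0.111 with fry. Without AG120_IFNg replicate 3, which held 0.436% mitochondrial counts, camera's adjusted p was 0.000718 for mitochondrially encoded genes (negative) and 2.39e-05 for histones (positive).

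Among the interferon and antigen genes, the interaction in log2 units was 1.86 ± 0.09 for CIITA, 2.98 ± 0.30 for IDO1, 0.67 ± 0.06 for CD274, 2.98 ± 0.17 for MX2, -1.05 ± 0.09 for NLRC5, -0.85 ± 0.10 for B2M and -1.96 ± 0.18 for IFI27 (SE, n = 3 per group). DUOX2 had 4.85 ± 0.18, DUOXA2 3.79 ± 0.19 (3.785), LAMP3 3.38 ± 0.30, KCTD14 2.98 ± 0.28, MUCL3 -2.53 ± 0.29, CLVS1 -2.10 ± 0.15, TENM2 -1.96 ± 0.13 and FBN1, a fibrillin, -1.84 ± 0.23. The fit gave CXCL10 6.25 ± 1.63 (1.625), a value that rests on 0 counts in the AG120 libraries and is at least 1.59 with these at the 3-count floor. Its adjusted p of 0.0264 (edgeR's quasi-likelihood test) became 0.0529 to 0.0916 without 1 of 5 libraries (DMSO replicates 1 and 3, AG120 replicates 1, 2 and 3). The fit gave PNMA6E -4.06 ± 1.00, but this rests on 0 counts in the DMSO libraries and is at most 0.61 with these at the floor, so that its direction is not fixed. Its adjusted p of 0.0203 became 0.0629 to 0.0696 without DMSO replicate 1, 2 or 3 or IFNg replicate 2. CGAS had 1.37 ± 0.34 with adjusted p = 0.0178, and 0.0512 without AG120 replicate 1. KRT7, a biliary keratin, had -0.28 ± 0.08 with adjusted p = 0.0250, and 0.0576 to 0.0714 without DMSO replicate 1 or 3, IFNg replicate 2 or 3, or AG120 replicate 1 or 3.

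Element reads fell by 25.4% relative to gene reads in AG120 vs DMSO (LINE, SINE, LTR, DNA and Retroposon elements outside ribosomal DNA regions), and 84.2% of that fall lay in introns on the strand of the host gene. The same fall in all element reads does not match the share in these introns, which changed by -7.17 percentage points in AG120. It was at 55.4% ± 1.35 against 62.6% ± 2.38 (SD, n = 3), with no overlap between the libraries. A rise of gene counts beside level element counts does not match as the whole cause. Gene counts do not enter the ratio of reads in these introns to reads outside genes, which changed by -15.5%. That ratio was at 5.95 ± 0.191 against 7.04 ± 0.374, again with no overlap. Both tests restate falls by position that were already seen, and chance gives no overlap in 10% of cases, so neither excludes its explanation. For the reads outside genes alone, which fell by 21.8%, such a rise of gene counts cannot be told apart from a fall of elements, since both give the same ratio and an external standard was not analysed here. Element reads over 50000 bases from any annotated gene fell by 32.7%, from 1293 ± 176 to 870 ± 33.7 CPM of effective gene counts (SD, n = 3). For these far reads this does not match transcripts running on from nearby genes, though a rise of gene counts would also lower them. Element reads outside genes but within 5000 bases of a gene fell from 10442 ± 752 to 8458 ± 287 CPM. For these the test cannot decide, since it used far reads only. In introns, fewer unspliced transcripts of the host genes cannot be told apart from an effect on elements there. Reads on the host strand per read on the opposite strand changed by -17.4%, at 16.1 ± 0.479 against 19.5 ± 1.26, but this ratio restates the falls already seen on both strands. The biological explanation, an effect of the inhibitor on elements, was not separated from these, and element reads were also lower with IFNg.

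AG120_IFNg replicate 3 stood apart from its partners, with 0.436% mitochondrial counts against 1.34% and 1.57%. A label exchanged with another group does not account for this, since its lower position on the inhibitor and interferon axes was 0.949, where 1 is the place of its partners. A loss of mitochondrial transcripts and nothing else does not either, since 1.15% of nuclear genes were 2-fold or more from its partners, where the highest library of the other groups had 0.137%. Leukocytes, fibroblasts or endothelial cells do not, since the higher of the 2 median log2 differences of their marker lists from its partners was -0.00527; this test covered no other cell type. No biological explanation was tested, since the library shares its group with its partners.

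Germline genes rose with the inhibitor in 34 of 42 cases. Of the 20 members outside multi-copy families, 15 (75%) rose, and reads shared within those families do not account for these rises. This count is no separate test. With 34 of 42 rising and 22 members in such families, most of the 20 had to rise. For the family members themselves, shared reads are not excluded. A general rise of genes of low level does not account for the rise of the list, since 100% of 10000 random lists matched on the DMSO level had a lower median than 3.06. The biological explanation that the design gives is the inhibitor itself, and the rise was also present with interferon, where 35 of 42 rose.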

How the results depend on the processing

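The alternative tests with reads on the element's own strand, without ribosomal DNA regions, without AG120_IFNg replicate 3 and with fry on element scaling were chosen only after the results were seen. Of 362 values for named genes, all kept direction and side of the threshold with DESeq2 and with RLE scaling, 361 without a filter and 359 with the replicate block. With only the 2 groups compared, 278 of 286 did, with 6 weaker and 2 stronger; leaving out each library in turn kept 4238 of 4344, with 93 weaker and 13 stronger. Counts of changed genes without 1 library were 8091 to 11886 in AG120 vs DMSO, 4480 to 9314 in IFNg vs DMSO, 8819 to 11234 in AG120_IFNg vs IFNg, 6460 to 9346 in AG120_IFNg vs AG120 and 2033 to 5088 for the interaction. With the replicate block they were 9409, 5944, 9800, 7443 and 2530; replicate numbers correlated at -0.130 to 0.113 and 5 of 12 libraries correlated best with their own number. Depth was not varied; in simulated data, changes of 2-fold were recovered by edgeR in 6.67% to 27.8% of genes under 1 CPM in the group contrasts, and in 7.81% of single copies at most. Satellites had no member to test, and the planned use of uniquely mapped reads was not run, since the table has no such column. The cause of the differences below was not tested, except that fewer copies enter outside genes, on 1 strand or with a higher minimum count.

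With element scaling the subfamilies changed were 294 in AG120 vs DMSO, 274 in IFNg vs DMSO, 262 in AG120_IFNg vs IFNg and 61 for the interaction. Outside genes they were 618 in AG120 vs DMSO, 225 in AG120_IFNg vs IFNg, 187 in AG120_IFNg vs AG120 and 57 for the interaction, and without TMM factor 204 in AG120_IFNg vs AG120 and 65 for the interaction. Without 1 library they were 115 to 604 in AG120_IFNg vs IFNg, 124 to 416 in AG120_IFNg vs AG120 and 17 to 177 for the interaction. Copies changed with element scaling were 16430, 11163 and 20616 in AG120 vs DMSO, IFNg vs DMSO and AG120_IFNg vs IFNg, and 34746 with a higher minimum count in AG120 vs DMSO. Outside genes they were 5359, 2493, 5091 and 3503 in the 4 group contrasts, on the element's own strand 21793, 9792, 17036 and 11290, and without 1 library 15707 to 71343, 7578 to 34498, 17546 to 33615 and 14207 to 22316.

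Gene lists called by camera in the 5 contrasts were 15, 11, 21, 16 and 14; with an estimated correlation they were 9, 9, 10, 11 and 6, with fry 22, 16, 24, 23 and 17, and without AG120_IFNg replicate 3 camera called 15, 12, 18, 17 and 15. With fry 26 of these list results were stronger and 1 weaker. Element lists called in AG120 vs DMSO were 4 with element scaling (3 higher, 1 lower) and 20 with fry, all lower; fry with element scaling called 1. In IFNg vs DMSO they were 0 with an estimated correlation, 0 with the replicate block, 4 with element scaling (2 higher, 2 lower) and 18 with fry, all lower, and fry with element scaling called 5 (camera 1, and 3 at unadjusted p). In AG120_IFNg vs IFNg fry called HERV-K, HERV9 and LTR12, and L2 and CR1 lower with gene scaling. With element scaling it called young L1, HERV-L and the HERV-E group, whose medians were 0.0950, 0.0516 and 0.134. In AG120_IFNg vs AG120 it called 0 with gene and 5 with element scaling (camera 0 with both, and 2 at unadjusted p with gene scaling), and for the interaction an estimated correlation, element scaling and fry gave 0 each (camera 1, and 2 at unadjusted p).

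As a share of all element counts the log2 changes in the 4 group contrasts were -0.119, -0.114, -0.0995 and -0.0943 for LINE, and -0.0143, 0.03875, -0.00839 and 0.0447 for SINE elements. They were -0.0641, -0.0006285, -0.00548 and 0.0580 for LTR, -0.128, -0.128, -0.158 and -0.158 for DNA, and 0.151, 0.0960, 0.105 and 0.0498 for Retroposon elements. The DNA values include ribosomal DNA regions. In DMSO, DNA elements were at 43105 CPM of effective gene counts with these regions and 23414 without. Relative to gene counts, the DNA changes were -0.504, -0.447, -0.362 and -0.305 with them, and -0.426, -0.343, -0.232 and -0.150 without. The lower DNA share may thus lie largely in ribosomal sequence. The Retroposon change in AG120 vs DMSO without TMM factor was -0.33. The correlation of the inhibitor's effects across genes, which are not independent replicates, was 0.789 for genes of a mean log2 CPM of at least 3 and 0.775 to 0.805 without 1 library.

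Direction was reversed outside genes for HERVKC4-int at -0.77 in AG120 vs DMSO, -0.35 in IFNg vs DMSO and -0.16 in AG120_IFNg vs IFNg, and in AG120 vs DMSO for HERVL18-int at -0.16, LTR18A at -0.22 and MamGyp-int at -0.38. It was reversed there in IFNg vs DMSO for MST-int at -0.74, LTR48 at -0.36 and LTR1F2 at 0.0728, in AG120_IFNg vs AG120 for MST-int at -0.23 and LTR21B at -0.18, and in the interaction for LTR47B2 at 1.11 and MamGypLTR1b at 0.19. On the element's own strand it was reversed for MamRep4096 at -0.69 in AG120 vs DMSO and -0.30 in IFNg vs DMSO, and for LTR48 at -0.19 in IFNg vs DMSO. In AG120_IFNg vs IFNg LSU-rRNA_Hsa was at -0.42 and SSU-rRNA_Hsa at -0.34 without ribosomal DNA regions, and SSU-rRNA_Hsa ranged from -0.27 (without AG120_IFNg replicate 3) to 2.11 without 1 library.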

Other observations

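No tests were chosen here after the results were seen; the values are counts from all regroupings of the libraries.

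With 3 libraries per group there are 10 splits of each pair of groups, which cannot give a share under 0.05. Every split but the real one mixes libraries of both groups, so the treatment effect enters its spread and partly its difference. The counts in the other splits therefore cannot show how many calls would arise without a treatment effect. For changed genes 1 of 10 splits, the real one, gave as many in each group contrast: 9685 in AG120 vs DMSO, 6412 in IFNg vs DMSO, 10018 in AG120_IFNg vs IFNg and 7773 in AG120_IFNg vs AG120, with 0 as the highest other each time (edgeR's quasi-likelihood test). For subfamilies 1 of 10 did as well, with 956, 873, 507 and 318 real and 0, 1, 0 and 0 in the highest other, and for a random subset of copies 1 of 10, with 4785, 2193, 3119 and 2139 real and 1, 1, 4 and 3 in the highest other. For gene lists 1 of 10 splits gave as many camera calls, with 15, 11, 21 and 16 real and 14, 10, 15 and 14 in the highest other. For element lists 10, 7, 10 and 10 of 10 splits gave as many, with 0, 1, 0 and 0 real (1, 3, 3 and 2 at unadjusted p; fry 20, 18, 3 and 0) and 0, 3, 8 and 7 in the highest other.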
